A study of Homo sapiens with 4 samples.

How the data were processed

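RNA of ARP-1 and MM.1S, human cell lines of multiple myeloma (a cancer of plasma cells), was measured on 4 whole-transcript microarrays, 1 array for each line and condition. Per the labels' protocols, cells received a lentivirus with a short hairpin RNA, either a control hairpin (CTR-KO) or a hairpin against MIF (MIF-KO), and cells positive for the green marker were sorted. A hairpin lowers a transcript and does not remove the gene, so the name KO stands here for a knockdown. Groups were taken from the titles and genotype labels, which name the same condition for every array. The free-text descriptions of both ARP-1 arrays name the opposite condition, and an exchange of these arrays was therefore planned as an alternative. Nothing in the labels tells of separate cultures, so any p-value rests on these 4 samples alone. In the main fit its error is how far the lines disagree in their differences, which can also be technical.

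The deposited values are probe set intensities on a linear scale for 53617 probe sets. RMA and limma are named in the submitters' processing notes, with no version or role given. The background step, the annotation and the genome build are not given in the sources used here. The design fixed before the data were examined took the deposited values to be log2. Their range, from 2.74 to 15935 over the 4 arrays, showed linear intensities, and log2 was taken of them with no pseudocount. RMA gives no depth or detection call, so the number of arrays limits the precision.

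A platform annotation gave 1 gene symbol for 16098 probe sets and several symbols for 0. The other 37519 probe sets are unnamed here. All 16098 symbols matched a current RefSeq gene by Entrez ID (assembly GRCh38.p14, used for names alone), and 0 were renamed. No coordinates are given, because no build is named for the arrays. For the 779 of 14884 genes with several probe sets, the probe set with the highest mean stood for the gene. Genes with a mean at or above the median of all gene means (4.97 on the log2 scale) were tested, 7442 in number.

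The model was limma (version 3.58.1, R 4.3.3) with the terms cell line and condition, then eBayes with a trend. Cell line is the pairing and comes from the labels. Across genes, the deviations of same-line arrays from their condition means correlated at r = -0.37, so the arrays of a line did not deviate together. The fit leaves 1 residual degree of freedom, which is the difference between the lines in MIF-KO minus CTR-KO, and the variance prior added 3.99. Opposite responses of the lines thus enter the error of every gene's tests, of condition and of line alike. Benjamini-Hochberg adjustment ran over all tested genes, with a threshold of 0.05. Differences are MIF-KO minus CTR-KO on the log2 scale. Within a line there is 1 array per condition, so differences per line are given with no error and no test. The exception is an interval for MIF in ARP-1 in the closing section, which borrows the posterior SD of the fit over both lines. For the same reason the difference between the responses of the lines could not be tested.

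Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists that had a tested member. Histone genes were not tested, since 0 of the 44 members were named here. Per line, the median of each list was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes those arrays and is no test. A list outside the central 95% lay under percentile 2.5 or over 97.5. List members were also tested with an adjustment over the list alone.

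Named genes followed a rule fixed beforehand. It takes MIF, then up to 12 genes per direction past the threshold in the same direction in both lines. Free places went to the genes of smallest p that differed at least 1.5-fold the same way in both lines, which are named as not having passed. It adds the 5 largest differences per line and direction, 8 genes per direction between lines, and up to 4 members per list by size of the mean difference. Symbols of listed kinds (such as microRNAs, long intergenic RNAs, open reading frames and genes of the Y chromosome) were not named, while pseudogenes and other non-coding genes could be.

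The model was tested on simulated data: 20 runs of 7442 genes with 200 changed, for MIF-KO against CTR-KO. It recovered 2.2% of genes changed 2-fold, 51% of those changed 4-fold, 92.1% of those changed 8-fold and 98% of those changed 16-fold, with 205 false calls among 2639. At an unadjusted p below 0.05, camera found a list with all members shifted alike in 20 of 20 runs and an unshifted list in 0. The adjustment over lists used for the real data was not part of this check. The shift was larger than the median difference of every list called in the real data except ATF4 targets. Smaller shifts were not tried. The simulated noise was independent between genes, with no correlation within lists and no opposition between lines. These rates therefore need not hold for the real arrays, and they do not show how often camera calls a correlated list falsely.

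Alternatives planned were no filter and a stricter filter on dim genes, arrays shifted to the same median, quantile normalization, the mean of the probe sets of a gene, no trend in the variance prior and no cell line term. Further planned ones were the ARP-1 arrays exchanged, each pair or array left out, thresholds of 1.3-fold and 2-fold, camera with an estimated correlation or on ranks, and the line comparison without condition. With an estimated correlation, camera rests on the 1 residual degree of freedom, so hardly any list could pass. A call lost under that setting is therefore weak evidence against a list. Use of named and unnamed probe sets alike, filtered at their own median, and a crossed pairing were added after seeing the data.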

Results

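Gene expression was compared between MIF-KO and CTR-KO cells of ARP-1 and MM.1S, lines of human multiple myeloma, on 4 arrays. Each condition had n = 2 arrays, 1 from each line. The question the design poses is which genes differ when MIF, a secreted inflammatory cytokine, is lowered by a hairpin RNA. The median probe set intensities were 13.1 for CTR-KO ARP-1, 13.2 for MIF-KO ARP-1, 13.1 for CTR-KO MM.1S and 13.3 for MIF-KO MM.1S. Arrays are called by their titles, since the descriptions of both ARP-1 arrays name the opposite condition.

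MIF (probe set 16928098) was lower on the MIF-KO array of each line. Its intensity was 1092 on the CTR-KO array and 541 on the MIF-KO array of ARP-1, 49.6% of control. In MM.1S it was 1012 and 405, 40% of control. The mean log2 difference was -1.17 (SE 0.29, n = 2 lines), with a 95% interval from -1.92 to -0.42, or 26.5% to 74.9% of control. MIF had the smallest p of all 7442 tested genes, yet its limma adjusted p over all of them was 0.99995. Adjusted over MIF alone, a single test, its limma adjusted p was 0.0104. Within ARP-1 it ranked 204 from the most lowered gene, and within MM.1S it ranked 9. The direction in ARP-1 follows the titles and runs against the descriptions: with the ARP-1 arrays exchanged, the mean difference was -0.15.

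**Figure D1:**
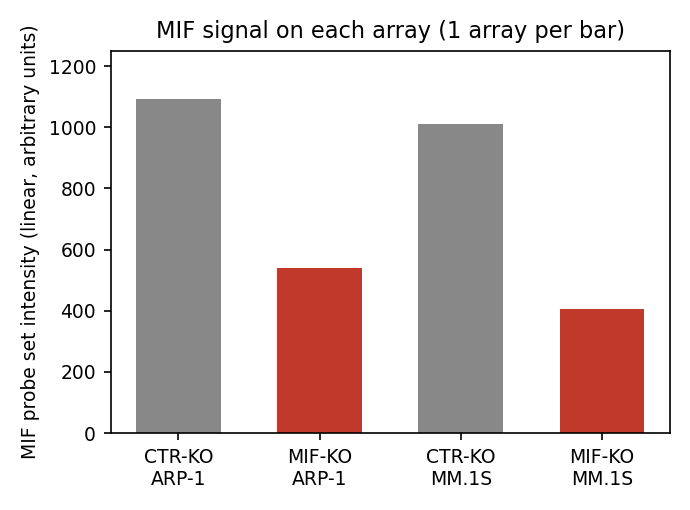
MIF probe set intensity (linear, arbitrary units, vertical axis from 0) on each of the 4 arrays; each bar is 1 array, grey for CTR-KO and red for MIF-KO, with no error bar. The MIF-KO bars, at 541 in ARP-1 and 405 in MM.1S, are below the CTR-KO bars at 1092 and 1012.

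Beyond MIF, few genes differed in the same direction in both lines. BMAL2, a transcription factor of the circadian clock family, was higher in MIF-KO by 0.93 in ARP-1 and 0.83 in MM.1S (mean 0.88, SE 0.26). KLHL6, a ubiquitin ligase adaptor of B cells, was higher by 0.69 and 1.09 (mean 0.89, SE 0.29). OTUD1, a deubiquitinase, differed by -1.10 and -0.93 (mean -1.02, SE 0.26). FRRS1, a ferric reductase, differed by -0.84 and -0.70 (mean -0.77, SE 0.22). With MIF and the microRNA gene MIR4526, which the naming rule leaves out and which was named after its values were seen, these are the 6 genes at least 1.5-fold apart the same way in both lines, 2 higher and 4 lower. Independent lines would give 67.1. None passed the test: limma called 0 of 7442 genes at an adjusted p below 0.05, the lowest adjusted p was 0.99995, and 29 genes had an unadjusted p below 0.05 (16 higher and 13 lower, against 372.1 by chance). The error in these tests is the disagreement of the lines, so the 0 calls also reflect their opposition. Once the ARP-1 arrays were exchanged as described, 401 genes passed.

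Genes that differed in both lines mostly did so in opposite directions. At 1.5-fold, 363 genes differed in opposite directions, where independent lines would give 68.8: 241 were lower in MIF-KO ARP-1 and higher in MIF-KO MM.1S, and 122 the reverse. Across the 7442 genes the differences of the lines correlated at Pearson r = -0.55 and Spearman rho = -0.53. Genes are not independent replicates, and no test of the opposition exists with 1 array per line and condition. Of the sum of squares between arrays, 18.5% lay along condition, 26.3% along line and 55.2% along the difference in response between lines. With the ARP-1 arrays exchanged, r turned to 0.55 and 363 genes differed the same way.

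**Figure D2:**
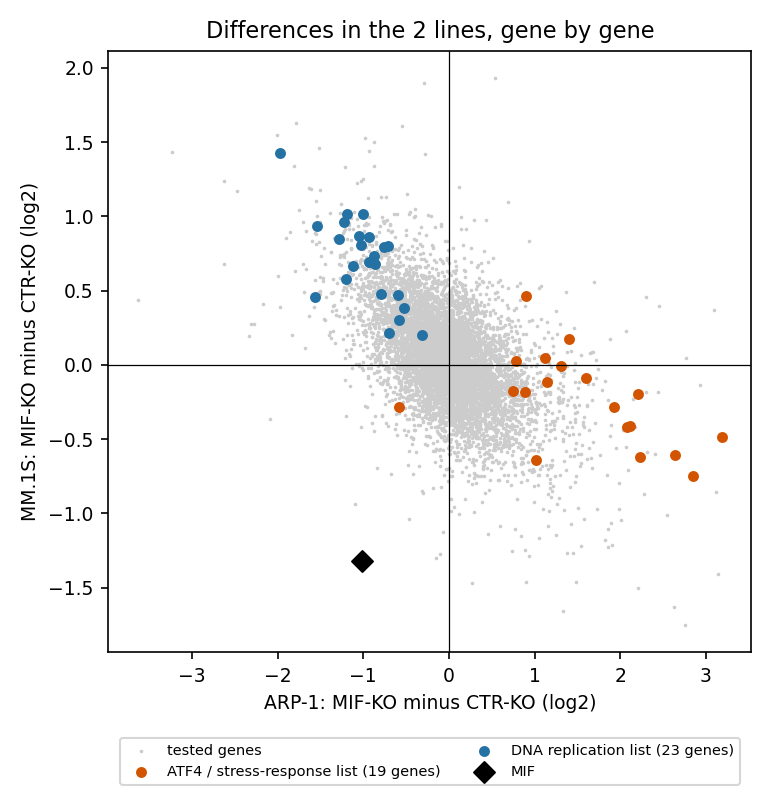
MIF-KO minus CTR-KO (log2) in ARP-1 on the horizontal axis and in MM.1S on the vertical axis, 1 point per tested gene; colours mark the 19 tested ATF4 targets and the 23 tested DNA replication genes, and the diamond marks MIF. The cloud slopes downward (r = -0.55), while MIF sits at -1.01 and -1.32.

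The ARP-1 pair showed the wider differences, with 809 genes at least 1.5-fold higher and 888 lower in MIF-KO, and 43 genes at least 4-fold apart. This width goes with the CTR-KO ARP-1 array, which lay as far from CTR-KO MM.1S (44 genes 4-fold apart), while MIF-KO ARP-1 and CTR-KO MM.1S had 2 such genes. The largest positive differences were in CTH, the cystathionine gamma-lyase of cysteine synthesis, at 3.19, the galectin pseudogene LGALS17A at 3.14, the vesicle protein SYT11 at 3.12, the endocytic protein EHD3 at 3.10 and the nuclear receptor corepressor NRIP1 at 2.93. The largest negative differences were in ANXA1, a phospholipid-binding annexin, at -3.63, the actin-like ACTL8 at -3.23, the membrane repair protein MYOF at -2.63, the RNase P subunit RPP40 at -2.62 and the lipopolysaccharide receptor TLR4 at -2.48. In MM.1S these genes differed by -0.49 (CTH), -1.41 (LGALS17A), -0.86 (SYT11), 0.37 (EHD3), -0.13 (NRIP1), 0.44 (ANXA1), 1.43 (ACTL8), 1.24 (MYOF), 0.68 (RPP40) and 1.17 (TLR4). These differences rest on 1 array per condition and have no replicate check. On the CTR-KO array LGALS17A (log2 3.05) and NRIP1 (3.26) lay below the median of all probe sets (3.72), so the sizes and ranks of their differences are uncertain.

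MM.1S had 381 genes at least 1.5-fold higher and 215 lower in MIF-KO, and 0 genes 4-fold apart. The largest positive differences were in GPR183, an oxysterol receptor that guides B cells, at 1.93, the interleukin-6 receptor IL6R at 1.90, adenosine deaminase ADA at 1.63, the immune checkpoint ligand HHLA2 at 1.61 and the RNA polymerase III subunit POLR3G at 1.55. The largest negative differences were in the non-coding HCP5 at -1.75, the endocytic REPS2 at -1.66, argininosuccinate synthase ASS1 at -1.63, the unfolded protein sensor ERN1 at -1.50 and the transcription factor JUN at -1.46. In ARP-1, GPR183 differed by 0.53, IL6R by -0.29, ADA by -1.78, HHLA2 by -0.55 and POLR3G by -2.003. HCP5 differed there by 2.75, REPS2 by 1.33, ASS1 by 2.62, ERN1 by 2.20 and JUN by 1.49. These also rest on 1 array per condition.

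Targets of ATF4, the transcription factor of the integrated stress response, formed the most displaced list in ARP-1. Of 19 tested members, 18 were at least 1.5-fold higher in MIF-KO ARP-1, with a median of 1.40 (percentile 100 of matched random lists), and in MM.1S 4 were lower and 0 higher, with a median of -0.20 (percentile 0.14). CTH is a member. The leucine sensor SESN2 differed by 2.85 in ARP-1 and -0.75 in MM.1S, the secreted STC2 by 2.64 and -0.61, and asparagine synthetase ASNS by 2.21 and -0.20. The CTR-KO ARP-1 array stood apart from the other 3 arrays: relative to each gene's mean, the list's median was -1.20 there, 0.36 on MIF-KO ARP-1, 0.53 on CTR-KO MM.1S and 0.29 on MIF-KO MM.1S. Over both lines the list rose (median 0.76, camera adjusted p = 1.2e-09), a call lost with an estimated correlation (adjusted p = 0.95 with an estimated correlation). Without the ARP-1 pair the median was -0.20, and with the ARP-1 arrays exchanged the list fell (adjusted p = 1.5e-09).

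Glycolysis and hypoxia-response genes rose over both lines (18 tested, median 0.16, camera adjusted p = 0.044), and lost the call with an estimated correlation (adjusted p = 0.95 with an estimated correlation). Their median was 0.48 in ARP-1 (percentile 100, 7 members at least 1.5-fold higher and 1 lower) and -0.02 in MM.1S (percentile 19.8). The mTORC1 inhibitor DDIT4, which is also on the ATF4 list, differed by 1.93 and -0.28. The peptide hormone ADM differed by 1.15 and 0.22, VEGFA by 1.28 and -0.31 and NDRG1 by 1.41 and -0.48. Here too CTR-KO ARP-1 stood apart, with a median of -0.33 relative to each gene's mean, against 0.09 on MIF-KO ARP-1, 0.02 on CTR-KO MM.1S and 0.11 on MIF-KO MM.1S. Exchange of the ARP-1 arrays turned the list downward (adjusted p = 0.047). The call was lost without the filter (adjusted p = 0.29), without the cell line term (adjusted p = 0.093) and on ranks (adjusted p = 0.057).

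DNA replication genes stood at opposite extremes in the lines. All 23 tested members were lower in MIF-KO ARP-1, 20 of them at least 1.5-fold (median -0.94, percentile 0), and all 23 were higher in MIF-KO MM.1S, 15 of them at least 1.5-fold (median 0.73, percentile 100). GINS2, of the replicative helicase, differed by -1.97 in ARP-1 and 1.42 in MM.1S, GINS1 of the same complex by -1.20 and 0.58, the origin factor MCM10 by -1.54 and 0.93, and the checkpoint mediator CLSPN by -1.56 and 0.46. Over both lines the median was -0.11 and the list missed the threshold (camera adjusted p = 0.10), though it passed on ranks (adjusted p = 0.046; adjusted p = 0.95 with an estimated correlation). With the ARP-1 arrays exchanged it rose by a median of 0.89 (camera adjusted p = 2.4e-16), which restates its opposite directions in the lines.

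MYC targets, mostly genes of ribosome assembly, were displaced like the DNA replication genes. Their median was -0.63 in ARP-1 (percentile 0, 12 of 21 at least 1.5-fold lower) and 0.36 in MM.1S (percentile 99.97, 3 higher). The ribosome assembly factors RRS1 differed by -2.17 and 0.41, RRP12 by -1.37 and 0.48, TCOF1 by -1.16 and 0.34, and the helicase DDX21 by -0.81 and 0.05. The list fell over both lines (median -0.13, camera adjusted p = 0.018; adjusted p = 0.95 with an estimated correlation). It rose with the ARP-1 arrays exchanged (adjusted p = 1.7e-06), and the unfiltered call was lost (adjusted p = 0.22). Relative to each gene's mean, the median of the MYC list was highest on CTR-KO ARP-1, at 0.44. It was -0.26 on MIF-KO ARP-1, -0.23 on CTR-KO MM.1S and 0.08 on MIF-KO MM.1S.

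Cytosolic ribosomal protein genes fell by a small amount (30 tested, median -0.08, camera adjusted p = 0.024; adjusted p = 0.95 with an estimated correlation). Their medians were -0.12 in ARP-1 (percentile 20.6) and -0.07 in MM.1S (percentile 3.23). RPS16 differed by -0.37 and -0.35, RPS15A by 0.19 and -0.90, RPL19 by -0.02 and -0.56, and RPS9 by -0.18 and -0.33. The call was lost without the filter (adjusted p = 0.23), with the stricter filter (adjusted p = 0.063) and with the ARP-1 arrays exchanged (adjusted p = 0.83). Mitosis genes did not pass (25 tested, median -0.05, adjusted p = 0.52). Their medians were -0.21 in ARP-1 (percentile 8.04) and 0.15 in MM.1S (percentile 90.1), with BUB1 at -0.33 and -0.21, PLK1 at -0.28 and -0.03, CDCA8 at -0.39 and 0.08, and CDC20 at -0.22 and -0.06. The mitosis list passed upward with the ARP-1 arrays exchanged (adjusted p = 0.048).

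Oxidative phosphorylation subunits fell over both lines (13 tested of 72 members, median -0.12, camera adjusted p = 0.018; adjusted p = 0.95 with an estimated correlation). CYC1 of complex III differed by -0.70 in ARP-1 and 0.04 in MM.1S, UQCRH by -0.41 and -0.20, COX7A2 of complex IV by -0.35 and -0.25, and COX6B1 by -0.19 and -0.35. The medians were -0.27 in ARP-1 (percentile 5.26) and 0.04 in MM.1S (percentile 52.2), the latter turning negative when arrays were shifted to the same median (-0.01). The call was lost without the filter (adjusted p = 0.22), with the stricter filter (adjusted p = 0.063) and with the ARP-1 arrays exchanged, where the direction turned (adjusted p = 0.22).

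Mitochondrial chaperones, proteases and import genes had a median of -0.44 in ARP-1 (percentile 0.16) and 0.23 in MM.1S (percentile 98.3), and did not pass over both lines (21 tested, median -0.09, adjusted p = 0.35). The import pore TOMM40 differed by -1.31 and 0.55, TIMM10 by -1.05 and 0.36, TIMM13 by -0.95 and 0.31, and TIMM17A by 0.02 and 0.50. This list passed upward with the ARP-1 arrays exchanged (adjusted p = 0.0014). Antioxidant genes did not pass (20 tested, adjusted p = 0.83). Their median over both lines was 0.02, while their mean was -0.01 and the test pointed down. Heme oxygenase HMOX1 differed by -1.01 and 0.10, PRDX1, a peroxidase that binds MIF, by -0.87 and 1.501, MSRA by -0.59 and 0.10, and GLRX2 by -0.30 and 0.75. The antioxidant medians were -0.31 in ARP-1 (percentile 1.8) and 0.14 in MM.1S (percentile 87.0), and with the ARP-1 arrays exchanged the list passed upward (adjusted p = 0.026).

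Of the protein-folding lists, cytosolic heat-shock genes had medians of -0.46 in ARP-1 (percentile 0.41) and 0.23 in MM.1S (percentile 95.5), with no call over both lines (12 tested, median -0.11, adjusted p = 0.56). HSPH1 differed by -1.70 and 0.96, HSPA1A by -0.52 and -0.15, HSPA1B by -0.53 and -0.07, and CHORDC1 by 0.14 and 0.91. HSPA1A and HSPA1B are near-identical copies, so their probe sets can share signal. Endoplasmic reticulum chaperones were not called (17 tested, adjusted p = 0.94). Their median was 0.23 in ARP-1 (percentile 97.9) and -0.08 in MM.1S (percentile 5.01). Over both lines the median was -0.01 and the test pointed down, while the mean was 0.03. Next to ERN1, SDF2L1 differed by -0.80 and 0.03, ERO1B by 1.01 and -0.39, and ATF6 by 0.47 and 0.10. With the ARP-1 arrays exchanged, the heat-shock list passed upward (adjusted p = 0.026) and the endoplasmic reticulum list downward (adjusted p = 0.028).

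The proteasome list had 1 tested member of 39, the assembly factor POMP, at -0.75 in ARP-1 (percentile 6.23) and 0.36 in MM.1S (percentile 80.8; adjusted p = 0.72). Autophagy and lysosome genes had a median of 0.21 in ARP-1 (percentile 98.8) and -0.14 in MM.1S (percentile 0.90), with no call over both lines (25 tested, median 0.04, adjusted p = 0.85). The autophagy receptor OPTN differed by 1.82 and -1.18, GABARAPL1 by 1.37 and -0.58, cathepsin CTSZ by 1.14 and -0.43, and the sialidase NEU1 by -0.42 and -0.09. The autophagy list passed downward with the ARP-1 arrays exchanged (adjusted p = 0.011).

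Apoptosis genes had differences of both signs within each line, and neither list was called. BCL2, the survival factor, differed by 2.01 in ARP-1 and -1.05 in MM.1S, BCL2A1 by -1.48 and 0.59, CFLAR by 1.04 and -0.58, and survivin BIRC5 by -0.45 and -0.28. Among inducers of apoptosis, BAK1 differed by -1.84 and 0.20, BCL2L11 by 1.54 and -0.66, PMAIP1 by 0.49 and 0.18, and APAF1 by 0.07 and 0.55. The anti-apoptotic list (10 tested) had medians of 0.08 in ARP-1 (percentile 77.4) and -0.12 in MM.1S (percentile 7.3), and the pro-apoptotic list (10 tested) of -0.03 (percentile 56.4) and 0.16 (percentile 82.2). Each had an adjusted p of 0.91. Their medians over both lines, 0.02 and 0.004, were near 0 and changed sign with the scaling of the arrays, and both tests pointed down. Of the p53 targets (11 tested, adjusted p = 0.91), SESN2 led, TRIAP1 differed by -1.13 and -0.02, RRM2B by 0.54 and 0.44, and AEN by -1.07 and 0.44. The p53 list had medians of 0.12 in ARP-1 (percentile 84.9) and -0.20 in MM.1S (percentile 1.37). Over both lines its median was -0.06 and its mean 0.04, and the test pointed down.

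Of the known partners of MIF, the receptor CXCR4 differed by 0.72 in ARP-1 and -0.12 in MM.1S, the co-receptor CD44 by -0.89 and 0.43, the signalosome subunit COPS5 by -0.80 and 0.02, and the paralog DDT by -0.01 and 0.36. With PRDX1 these are the 5 tested members. The list was not called (median 0.17, adjusted p = 0.96), with medians of -0.80 in ARP-1 (percentile 0.29) and 0.36 in MM.1S (percentile 96.6). Adhesion and homing molecules did not pass (12 tested, median 0.06, adjusted p = 0.79), with medians of 0.25 (percentile 96.3) and -0.05 (percentile 17.7). NCAM1 differed by 1.95 and -0.56, ALCAM by 1.27 and -0.23, CCR1 by -0.83 and 0.03, and syndecan SDC1 by -1.36 and 0.48. SDC1 also belongs to the plasma cell list, where CD38 differed by -1.44 and 0.46, ITM2C by -0.59 and 0.01, and CREB3L2 by 0.75 and -0.22. That list was not called (12 tested, median -0.10, adjusted p = 0.71), with medians of 0.10 in ARP-1 (percentile 83.1) and -0.03 in MM.1S (percentile 20.8).

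Immediate-early and feedback genes of ERK signalling had a median of -0.26 in ARP-1 (percentile 3.45) and 0.37 in MM.1S (percentile 100), with no call over both lines (20 tested, median 0.04, adjusted p = 0.75). The phosphatase DUSP2 differed by -1.97 and 0.39, ETV5 by 1.06 and 0.52, FOS by -0.21 and 1.003, and IER3 by -0.80 and -0.13. Targets of NF-kappaB were not called (11 tested, median -0.11, adjusted p = 0.10), with medians of 0.02 in ARP-1 (percentile 62.4) and -0.25 in MM.1S (percentile 0.39). Beside BCL2A1 and IER3, CD83 differed by -0.47 and -0.28 and the chemokine CCL5 by -0.39 and -0.09. Interferon-stimulated genes were not called (13 tested, adjusted p = 0.91), with medians of 0.10 (percentile 79.8) and -0.28 (percentile 0.06). Over both lines their median was -0.03 and their mean 0.02, and the test pointed down. USP18 differed by 0.29 and 0.97, SAMD9L by -0.95 and -0.28, UBE2L6 by 1.42 and -0.22, and IFITM3 by -0.42 and -0.34. Cholesterol synthesis genes were not called (20 tested, median 0.03, adjusted p = 0.91), with medians of 0.12 (percentile 93.1) and 0.002 (percentile 29.7), the latter turning to -0.05 with arrays shifted to the same median. FADS1 differed by 1.502 and -0.15, INSIG1 by 0.93 and 0.03, ACAT2 by -1.15 and 0.36, and NSDHL by -0.66 and 0.21.

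Markers of other cell types were few among the tested genes. Mature B cell markers, with 2 tested members, fell (median -0.30, camera adjusted p = 0.044; adjusted p = 0.95 with an estimated correlation): CD83, and the transcription factor SPIB at -0.41 in ARP-1 and -0.05 in MM.1S. The medians were -0.44 (percentile 6.93) and -0.17 (percentile 20.4). The call was lost without the filter (adjusted p = 0.98), with probe sets averaged (adjusted p = 0.80), without the cell line term (adjusted p = 0.056), on ranks (adjusted p = 0.085) and with the ARP-1 arrays exchanged, where the direction turned (adjusted p = 0.71). T and NK cell markers were not called (5 tested, adjusted p = 0.94), with medians of -0.32 (percentile 6.81) and 0.25 (percentile 91.8). Their median over both lines was 0.05, against a mean of -0.02. LAT differed by -1.05 and 0.002, GNLY by 0.19 and 0.63, ZAP70 by -0.40 and -0.003, and CD7 by 0.10 and 0.25. Monocyte markers were not called (5 tested, median 0.15, adjusted p = 0.72), with medians of 0.16 (percentile 78.5) and -0.12 (percentile 16.2). VCAN differed by 1.52 and -0.12, the lysosomal CD68 by -1.99 and 0.60, CST3 by 0.65 and -0.31, and S100A9 by 0.11 and 0.19. Of the stromal markers, fibronectin FN1 differed by 0.46 and -1.14 and VIM by -0.07 and -0.30 (2 tested, median -0.26, adjusted p = 0.31). Their medians were 0.19 (percentile 71.6) and -0.72 (percentile 0.15).

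Across all lists, 24 of 27 had medians of opposite sign in the lines. In ARP-1, 10 lists lay outside the central 95% of matched random lists, and 10 did in MM.1S. Random lists hold unrelated genes, and members of a fixed list can vary together, so more lists than chance gives can lie outside without any effect of condition. Camera called 6 of the 27 lists, 0 with an estimated correlation and 5 on ranks. The 0 does not show that correlation among members undid the calls. Ribosomal proteins (-0.030) and glycolysis (-0.0065) had estimated correlations under the preset 0.01 and lost their calls too. The other called lists had estimates above the preset. These were 0.79 for ATF4 targets, 0.64 for MYC targets, 0.44 for oxidative phosphorylation and 1 for mature B cell markers. Such estimates rest on 1 residual degree of freedom. The preset may still be too low for these lists, and their camera p-values too small. Adjusted over the list alone, 0 genes of any list passed, and 0 passed over all genes tested.

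**Figure D3:**
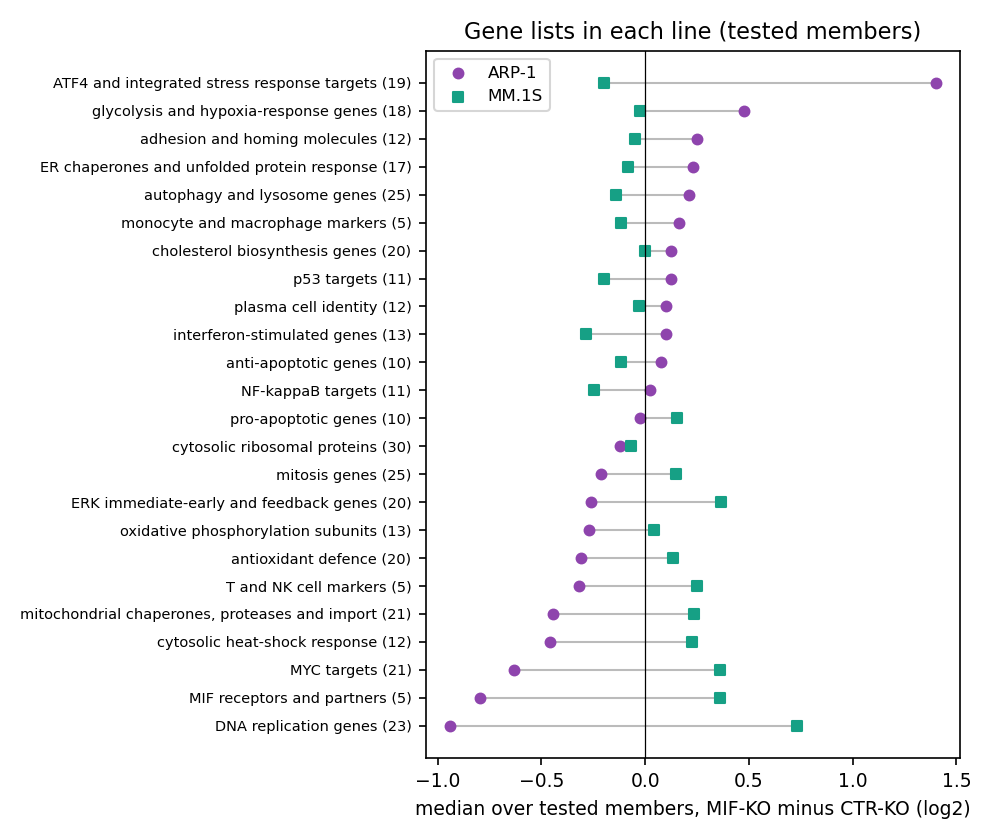
Median MIF-KO minus CTR-KO difference (log2, horizontal axis) over the tested members of each gene list with at least 5 of them, with circles for ARP-1, squares for MM.1S and the number of tested members in brackets; each point rests on 1 array per condition. ATF4 targets lie at 1.40 in ARP-1 and -0.20 in MM.1S, and DNA replication genes at -0.94 and 0.73.

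Between the lines, CD37, a tetraspanin of B cells, was lower in MM.1S than in ARP-1 by a mean difference of -1.50, with -1.45 on the CTR-KO arrays. PAPSS2 differed by -1.51, ZNF134 by -1.32, the actin regulator NCKAP1L by -1.15, ZNF8 by -1.06, ANGEL1 by -1.04, RFESD by -0.74 and USP49 by -0.70. Higher in MM.1S were DHX32 at 1.36, LURAP1L at 1.29, the peroxisomal PHYH at 1.25, MOCOS at 1.24, KIF26B at 1.04, the opsin OPN3 at 1.04, the pseudogene ADCY10P1 at 0.88 and the growth factor PDGFA at 0.81. None passed: limma called 0 of 7442 genes (87 at an unadjusted p below 0.05), and the lowest adjusted p was 0.99986. At least 4-fold the same way under both conditions, 0 tested genes separated the lines, and 1 gene was at least 2-fold higher and 4 lower in MM.1S. The SD over genes of the difference between arrays was 0.54 for the ARP-1 pair and 0.34 for the MM.1S pair. Between lines it was 0.55 for the CTR-KO arrays, 0.39 for the MIF-KO arrays, 0.39 between CTR-KO ARP-1 and MIF-KO MM.1S, and 0.31 between MIF-KO ARP-1 and CTR-KO MM.1S.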

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

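All tests of explanations below were chosen after the results were seen. The items of this part went in opposite directions in the lines: lists outside the central 95% of matched random lists on opposite sides, and named genes at least 1.5-fold apart in opposite directions. Each line had 1 array per condition, so the difference between lines was not tested.

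For lists, the MM.1S median minus the ARP-1 median was -1.60 for ATF4 targets, 1.67 for DNA replication genes, 0.99 for MYC targets, 0.68 for mitochondrial chaperones, proteases and import, and -0.35 for autophagy and lysosome genes. For 12 genes the MM.1S difference exceeded the ARP-1 difference: ACTL8 by 4.66, MYOF by 3.87, TLR4 by 3.65, POLR3G by 3.55, ADA by 3.41, GINS2 by 3.39, RPP40 by 3.30, HSPH1 by 2.66, CD68 by 2.59, MCM10 by 2.47, PRDX1 by 2.37 and BCL2A1 by 2.06. For the other 12 genes the MM.1S difference minus the ARP-1 difference was -4.55 for LGALS17A, -4.50 for HCP5, -4.25 for ASS1, -3.98 for SYT11, -3.71 for ERN1, -3.60 for SESN2, -3.25 for STC2, -3.06 for BCL2, -3.00 for OPTN, -2.99 for REPS2, -2.95 for JUN and -2.21 for BCL2L11. The value for LGALS17A rests on a CTR-KO ARP-1 signal (log2 3.05) below the median of all probe sets on that array (3.72), so its size and rank are uncertain.

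The opposition may come from exchanged ARP-1 arrays, as their descriptions read. The 401 genes and the lists that then pass restate the opposition and are no evidence for an exchange. MIF speaks against an exchange, at -1.01 by title in ARP-1. An exchange would put its ARP-1 intensity at 1092 with the MIF hairpin and 541 with the control hairpin. Its 95% interval, which borrows limma's posterior SD from the fit over both lines, reached from -2.07 to 0.05. That SD holds the opposition which an exchange is meant to explain, so the interval cannot decide the question. A one-sided bound of -0.18 had first been taken as the test with that interval already known, so the interval was put back in its place. A state of the cultures unrelated to the hairpin, such as stress against growth, may also place the arrays, with 66.2% of the variance on 1 component. Opposite responses of the lines to less MIF (r = -0.55) cannot be told apart from these explanations, because each line and condition has 1 array.

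Arrays of different lines differed no more than arrays of the same line, with a mean SD over genes of 0.41 against 0.44. Compression by the normalization stays open: 43 genes were at least 4-fold apart between the ARP-1 arrays, but the pairs without CTR-KO ARP-1 had at most 6. Line labels exchanged for 1 array of each line stay open too. At least 2-fold apart in opposite directions were 45 genes (2.67 by independence), a contrast with 55.2% of the sum of squares against 26.3% for line. These values are the opposition itself. At 4-fold 0 genes differed so, but the MM.1S pair had 0 genes that far apart in any direction. With the arrays regrouped as such an exchange would have it, the spread between lines over that within lines was 1.296. That ratio is higher than under the given labels. It did not reach 1.5, the limit over which cells of 1 line or of closely related lines would have been rejected here. It also lay above the lower limit under which such cells would have been accepted, so it decides neither way. The ratio of spreads under the given labels, 0.93 (1.05 without CTR-KO ARP-1), is what cells of 1 line or of closely related lines on all 4 arrays would give, so a mix-up of cultures is a candidate explanation. Exchanged line labels can give a ratio this low as well, so it does not tell these explanations apart. A likeness of ARP-1 and MM.1S themselves stays open, as no other array of either line was used here.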

How the results depend on the processing

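Use of named and unnamed probe sets alike, filtered at their own median, and the crossed pairing were chosen after seeing the data. The difference in MIF kept its direction under all 10 alternatives tried, from -1.32 to -0.15, and did not pass the threshold over all tested genes in any of them that had a test. MIF has 1 probe set and the design is balanced, so the filters, averaging, trend and cell line term could not move its value. With the ARP-1 arrays exchanged, MIF turned upward in ARP-1, and only its mean with MM.1S (-1.32) stayed negative. Except for the exchange of the ARP-1 arrays, every alternative tried called 0 genes between MIF-KO and CTR-KO, including the fit with no cell line pairing (0 genes) and the crossed pairing (0 genes, 159 at an unadjusted p below 0.05). Each array left out in turn, with the lone remaining array of a condition assumed to vary like the others, also gave 0. The line comparison gave 0 genes under every alternative tried. A shift of the arrays to the same median and quantile normalization changed no call. The pairing by line changed no call beyond those named. Signal over background was not measured, so what dim signals limit is not known. The causes were not tested.

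An exchange of the ARP-1 arrays turns the opposition between the lines into the condition difference. It gave 401 genes that passed, 363 that differed the same way in both lines and an r of 0.55. List medians were then 0.30 for antioxidant genes, 0.11 for oxidative phosphorylation, 0.34 for mitochondrial chaperones, proteases and import, -0.17 for endoplasmic reticulum chaperones, -0.83 for ATF4 targets, 0.16 for mitosis, 0.89 for DNA replication, 0.50 for MYC targets, -0.29 for glycolysis and hypoxia, 0.27 for heat shock, -0.0076 for ribosomal proteins, -0.21 for autophagy and 0.14 for mature B cell markers. Of 134 named genes besides MIF, 37 passed, 34 of them in the turned direction. Mean differences turned to positive for ACTL8 (2.33), MYOF (1.93), TLR4 (1.82), POLR3G (1.77), ADA (1.71), GINS2 (1.70), RPP40 (1.65), HSPH1 (1.33), CD68 (1.296), RRS1 (1.29), MCM10 (1.23), BCL2A1 (1.03), CLSPN (1.01), CD38 (0.95), TOMM40 (0.93), RRP12 (0.93), SDC1 (0.92) and GINS1 (0.89). They turned to negative for LGALS17A (-2.27), HCP5 (-2.25), ASS1 (-2.13), SYT11 (-1.99), ERN1 (-1.85), CTH (-1.84), SESN2 (-1.80), STC2 (-1.62), BCL2 (-1.53), OPTN (-1.499), JUN (-1.47), NCAM1 (-1.26), BCL2L11 (-1.10), GABARAPL1 (-0.97), NDRG1 (-0.94) and CFLAR (-0.81).

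Without the filter, 24 genes differed the same way at 1.5-fold (62.9 by independence) and r was -0.41. In that setting 5 lists lost their call: oxidative phosphorylation (median -0.12), MYC targets (-0.13), glycolysis and hypoxia (0.13), ribosomal proteins (-0.080) and mature B cell markers (-0.027). The stricter filter left 1 gene the same way (36.3 by independence), and oxidative phosphorylation (-0.12) and ribosomal proteins (-0.082) lost their call. Mature B cell markers lost it with probe sets averaged (-0.042), and without the cell line pairing so did they (-0.30) and glycolysis (0.16). With an estimated correlation, where 1 residual degree of freedom lets hardly any list pass, all 6 called lists lost their call. Their medians were -0.12 for oxidative phosphorylation, 0.76 for ATF4 targets, -0.13 for MYC targets, 0.16 for glycolysis, -0.080 for ribosomal proteins and -0.30 for mature B cell markers. On ranks, DNA replication (-0.11) gained a call, and glycolysis (0.16) and mature B cell markers (-0.30) lost theirs. At 1.3-fold, 69 genes differed the same way (340.0 by independence), and at 2-fold 1 did (2.74). Over the 26809 probe sets, named or not, with a mean at or above the median of all probe sets, the count was 200 (295.5 by independence). There r was -0.37.

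With a pair of arrays left out, values carry no test. A single line gave 596 (MM.1S) to 1697 (ARP-1) genes at 1.5-fold. List medians ranged from -0.27 to 0.045 for oxidative phosphorylation, -0.20 to 1.40 for ATF4 targets, -0.63 to 0.36 for MYC targets and -0.025 to 0.48 for glycolysis, so each changed sign without the ARP-1 pair.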

Other observations

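Over all 53617 probe sets, named or not, 95 were at least 2-fold apart between the lines in the same direction under both conditions (38 higher and 57 lower in MM.1S). At 4-fold there were 2 higher and 3 lower, all of them among the 37519 unnamed probe sets and 0 among the 16098 named ones. The array of CTR-KO ARP-1 stood at one end of the first component, with a score of -0.77, and MIF-KO ARP-1 (0.45) and CTR-KO MM.1S (0.44) at the other, with MIF-KO MM.1S at -0.11.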
